A study of Mus musculus with 19 samples.

How the data were processed

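RNA abundance was measured on Affymetrix arrays in 19 samples of mouse hippocampus in 4 groups, made of 2 genotypes and 2 diets. The genotypes were APP-PS1, a transgenic model of amyloid plaque formation, and wild-type littermates on the C57BL/6J background. The diets were chow with ibuprofen at 375 ppm and the same chow without it, eaten from 3 to 6 months of age, when the tissue was taken. RNA was extracted with Trizol and RNeasy columns and labelled with a whole-transcript sense target kit, per the labels.

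The deposited values are log2 summaries per probe set, 1 column per array, made by the authors with Partek 6.5 and RMA per the submitters' processing notes. RMA usually corrects background and quantile-normalizes the arrays before it summarizes probes, but the settings used here are unknown. The scanner files were not used. Values ran from 3.46 to 14.80 and the array medians from 8.06 to 8.14, and no further normalization was applied. For arrays, their number limits the precision.

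The table held 35556 probe sets. An annotation of the array of 2016 gave 1 gene symbol to 21789 of them, several symbols to 1621 and none here to 12146, and 21698 of the Entrez gene numbers of the first kind matched a RefSeq gene table. Each gene was represented by the probe set with the highest mean over all arrays among those with its symbol alone, which left 19938 genes, 999 of them with more than 1 such probe set. No filter on dim genes was applied.

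Each array belonged to 1 of 4 groups by its genotype and diet label. One limma fit (limma 3.58.1 in R 4.3.3; data handling by the data.table package, version 1.17.8) held a mean per group for all arrays, with 15 residual degrees of freedom and an intensity trend in the empirical Bayes step, whose prior had 6.65 degrees of freedom. It gave 7 comparisons, which are genotype on each diet, ibuprofen in each genotype, the interaction of genotype and diet, and the averages of both effects. Tests were two-sided and p-values were adjusted by Benjamini and Hochberg over the 19938 genes, with a threshold of 0.05. Errors of differences are limma standard errors (SE) and errors of group means are standard deviations (SD).

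Of 36 gene lists fixed by name for pathways, cell types and neighbouring brain regions, 35 had at least 3 measured members and were tested with camera at a preset inter-gene correlation of 0.01. Camera asks whether the genes of a list differ from all other genes, so a list can pass with a median near 0. The same lists were run with camera's estimated correlation, and with fry, which asks whether the genes of a list move on balance 1 way. Over all genes the median difference was 0.02 for genotype on control chow and -0.05 on ibuprofen chow. It was -0.02 for ibuprofen in APP-PS1 mice, 0.05 in wild-type mice and -0.07 for the interaction. For the averages it was -0.01 for genotype and 0.01 for ibuprofen. Counts within a list are given over all genes and adjusted over the list alone. The microglia and macrophage list shares members with those of complement and Fc receptors, plaque-associated microglia and homeostatic microglia. These lists are therefore not separate evidence. Tdo2 is reported by the study these arrays belong to, so the lists that hold it are also given without it. The genes named were set by a rule: up to 10 of the largest rises and 10 of the largest falls past the threshold, the 10 genes with the smallest p where fewer passed, members of lists that passed, and a set of genes always given. Ptgs1, of that set, was not analysed here. Predicted genes without a standard name were counted and not named.

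Groups, comparisons, lists, the naming rule and most alternatives were set before the data were examined. The alternatives were another normalization, array centring, a filter on dim genes, other treatments of probe sets, other empirical Bayes settings, array weights, a fit of the compared groups alone, the replicate number as a block, covariates for choroid plexus, oligodendrocyte and sex-linked transcripts, and leaving out each array in turn. Leaving out the 3 arrays whose median correlation with the others lay under 0.99 was chosen after seeing the data. Under these alternatives and leave-outs the lists were run at the preset correlation only. A list call said to hold under every alternative therefore did not hold with an estimated correlation. The fit was tested on simulated data with the groups of this study, where it recovered 78% to 96% of genes changed by 0.5 on the log2 scale and 18% to 36% of those changed by 0.25 in the 4 comparisons of 2 groups. Unchanged genes made 0% to 8.33% of the simulated calls, with the highest share for genotype on ibuprofen chow. Each share rests on 1 simulated data set. The 5% of the threshold is an average over repeats, so 1 data set above it does not show that the threshold failed. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

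Sex, litter, scan date and batch are not in the labels. Beyond their titles, the labels do not say whether the replicates are separate animals, so p-values measure the spread between these samples.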

Results

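The data are 19 arrays of hippocampal RNA from mice 6 months old: 4 from wild-type mice on control chow, 5 from wild-type mice on ibuprofen chow, 5 from APP-PS1 mice on control chow and 5 from APP-PS1 mice on ibuprofen chow. APP-PS1 mice carry transgenes that cause amyloid plaques, and ibuprofen inhibits the cyclooxygenases that make prostaglandins. Array medians lay between 8.06 and 8.14 on the log2 scale, and pairs of arrays correlated at 0.970 to 0.997 across genes. APP-PS1 control chow replicate 1 and wild-type ibuprofen chow replicates 1 and 5 had median correlations with the others of 0.9895, 0.987 and 0.974, and stand apart in what follows. Ttr, the transthyretin gene and the most abundant transcript of the choroid plexus, varied widely in every group, with means of 11.85 ± 1.57 (SD, n = 4), 11.66 ± 1.29 (SD, n = 5), 12.46 ± 1.48 (SD, n = 5) and 12.95 ± 1.47 (SD, n = 5) in the order of groups above.

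App, the gene of the amyloid precursor protein (probe set 10440491), and Prnp, the prion protein gene whose promoter drives the transgenes of this line (probe set 10476314), were higher in APP-PS1 hippocampus on both diets. App stood at 13.20 ± 0.03 (SD, n = 4) in wild-type and 13.60 ± 0.02 (SD, n = 5) in APP-PS1 mice on control chow, and at 13.25 ± 0.10 (SD, n = 5) and 13.59 ± 0.03 (SD, n = 5) on ibuprofen chow. The App difference was 0.40 ± 0.04 (SE) on control chow, adjusted p = 3.3e-06, and 0.34 ± 0.03 (SE) on ibuprofen chow, adjusted p = 1.73e-05. Prnp differed by 0.67 ± 0.04 (SE), adjusted p = 8.19e-11, and by 0.67 ± 0.03 (SE), adjusted p = 2.54e-11. For both genes, each of the 5 APP-PS1 arrays on a diet lay above every wild-type array on it. For ibuprofen in APP-PS1 mice App gave -0.01 ± 0.03 (SE, adjusted p = 0.930).

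The first question was what the transgenes change in hippocampus on control chow. Prnp and App rose and no gene fell. Cst7, a cystatin that microglia make around plaques (probe set 10476945), gave a difference of 0.66 ± 0.12 (SE) with adjusted p = 0.0722, and Ccl3, a microglial chemokine (probe set 10389231), 0.84 ± 0.17 (SE) with adjusted p = 0.151. For both, 5 of 5 APP-PS1 arrays lay above every wild-type array. Arpp21, a neuronal phosphoprotein regulated by cyclic AMP (probe set 10597323), gave -0.34 ± 0.06 (SE) with adjusted p = 0.0533, and all 5 APP-PS1 arrays lay below every wild-type array.

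In the gene lists on control chow, 12 of 35 passed as higher and 2 as lower with the preset correlation, and 0 passed with an estimated correlation or with fry. All 17 measured cholesterol synthesis genes lay above 0 (median 0.22), with 0 called over all genes and 0 adjusted over the list alone. Camera gave adjusted p = 5.09e-08, but adjusted p = 0.609 with an estimated correlation. Hmgcs1, an early enzyme of the pathway, gave 0.24 ± 0.10 (SE). Oligodendrocyte markers had a median of 0.18 and 6 of 12 higher adjusted over the list alone, including Tspan2 at 0.39 ± 0.10 (SE) and Mal, a myelin protein gene, at 0.20 ± 0.05 (SE). Camera gave them adjusted p = 1.1e-05, and adjusted p = 0.609 with an estimated correlation. Genes of plaque-associated microglia, with 30 of 37 above 0 and a median of 0.10, had 0 called over all genes and 2 adjusted over the list alone, with camera adjusted p = 2.72e-05 and adjusted p = 0.609 with an estimated correlation. Immediate early genes, which neurons switch on with activity, were the clearest lower list, with 5 of 24 above 0, a median of -0.10 and camera adjusted p = 5.81e-06, but adjusted p = 0.609 with an estimated correlation. In it Nr4a1 gave -0.29 ± 0.10 (SE) and Arc -0.28 ± 0.13 (SE). The cholesterol median was 0.11 without APP-PS1 control chow replicate 1, and that of immediate early genes -0.06 without wild-type control chow replicate 3.

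Reactive astrocytes (median 0.11), microglia and macrophages (0.13), endothelial cells (0.15), complement and Fc receptors (0.14), amyloid processing and clearance (0.06), the heat shock and unfolded protein response (0.08), homeostatic microglia (0.09) and the mitochondrial respiratory chain (0.05) passed as higher on control chow, and neocortex and subiculum markers (-0.06) as lower. Each of these had adjusted p = 0.609 with an estimated correlation. Choroid plexus markers passed as higher as well, with 17 of 17 above 0, a median of 0.52 and camera adjusted p = 0.032. They had adjusted p = 0.852 with an estimated correlation. Per array, their mean was 10.25 and 9.85 in APP-PS1 control chow replicates 4 and 5 but 7.86 to 7.99 in replicates 1 to 3. In wild-type control chow it was 9.28 in replicate 1 and 7.73 to 8.19 in replicates 2 to 4. These genes thus varied together by array within both genotypes. The list median was 0.14 without APP-PS1 control chow replicate 4, 0.29 without replicate 5, 0.34 without wild-type control chow replicate 3 and 0.85 without replicate 1. The call ended with array weights (0.24), the replicate block (0.22), the oligodendrocyte covariate (0.29), the choroid plexus covariate built from these genes (0.03), median centring (0.53) and the dimmest genes left out (0.52). Of the 14 list calls, 6 held in every leave-out, namely cholesterol synthesis, oligodendrocytes, plaque-associated microglia, immediate early genes, reactive astrocytes and amyloid processing. Under every alternative at the preset correlation as well, 3 of these held, namely cholesterol synthesis, immediate early genes and reactive astrocytes. With the oligodendrocyte marker mean as a covariate, plaque-associated microglia did not pass (median 0.07, adjusted p = 0.0704), nor did amyloid processing (adjusted p = 0.361), nor oligodendrocytes, from which that mean is built (median 0.02, adjusted p = 0.756). Over the leave-outs the medians ran from 0.04 to 0.08 for amyloid processing, 0.09 to 0.23 for endothelial cells, 0.03 to 0.09 for the heat shock response, 0.08 to 0.16 for microglia and macrophages, 0.03 to 0.06 for the respiratory chain, -0.08 to -0.01 for neocortex and subiculum and 0.09 to 0.19 for reactive astrocytes. The other 8 of the 14 calls ended when APP-PS1 control chow replicate 1, 4 or 5 or wild-type control chow replicate 1, 2, 3 or 4 was left out, with adjusted p from 0.0553 to 0.985, the highest for choroid plexus without APP-PS1 control chow replicate 4.

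On control chow limma called 2 genes higher and 0 lower at the adjusted threshold, beside 1170 at an unadjusted p under 0.05, and 3 without the 3 arrays that stand apart, Ccl3 being the added gene (adjusted p = 0.0177, in a range of 0.00245 to 0.9997 over the alternatives). The count was 4 without APP-PS1 control chow replicate 2, where Arpp21 had adjusted p = 0.0195 and Vmn1r48, a vomeronasal receptor gene, adjusted p = 0.0156, and 4 without APP-PS1 ibuprofen chow replicate 1, where Arpp21 and Cst7 both had adjusted p = 0.0457. Cst7 passed as well without APP-PS1 control chow replicate 3 (adjusted p = 0.0413) or 4 (adjusted p = 0.0344), Ccl3 without wild-type ibuprofen chow replicate 1 (adjusted p = 0.0266), and Arpp21 without APP-PS1 ibuprofen chow replicate 3 or 4, wild-type control chow replicate 2 or wild-type ibuprofen chow replicate 5 (adjusted p = 0.0342 to 0.0462). The count at an unadjusted p under 0.05 was 400 without wild-type control chow replicate 3, 729 without APP-PS1 control chow replicate 1 and 1817 without wild-type ibuprofen chow replicate 5.

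**Figure D1:**
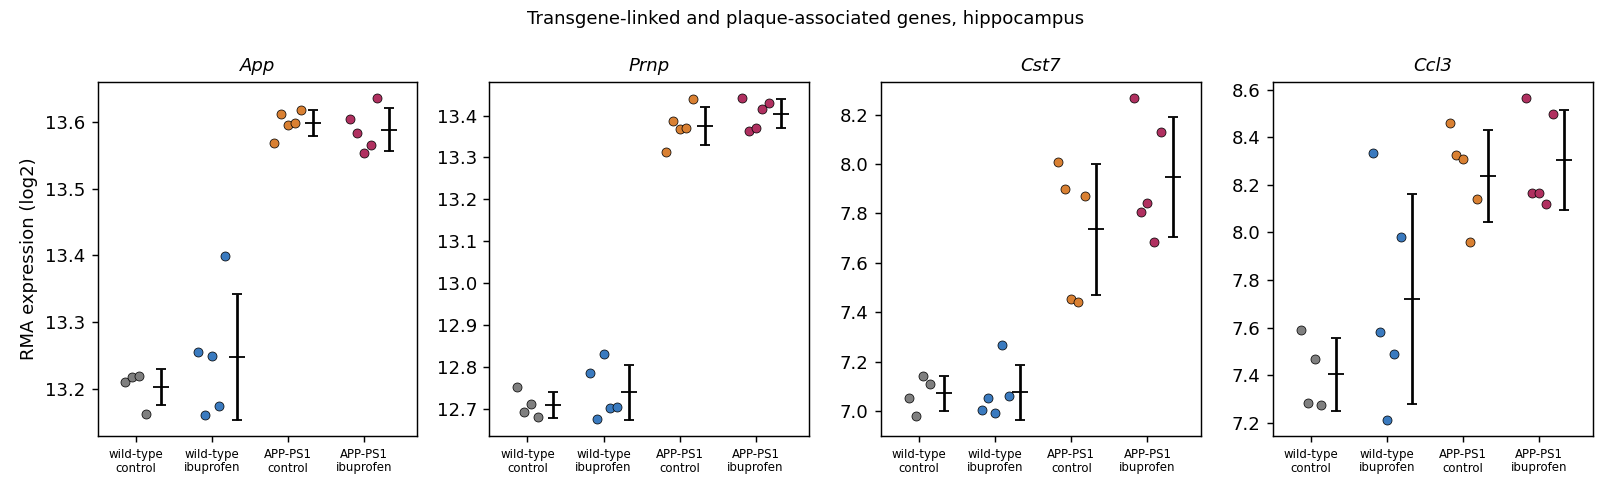
Log2 expression of App, Prnp, Cst7 and Ccl3 in each array, by group; points are arrays and the dash with its bar is the group mean ± SD. For App and Prnp all APP-PS1 arrays lay above all wild-type arrays of the same diet, and for Cst7 as well, while Ccl3 overlapped on ibuprofen chow.

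Averaged over both diets, the genotype comparison rested on all arrays, and 4 genes rose and 1 fell. Cst7 rose by 0.77 ± 0.08 (SE, adjusted p = 4.2e-05), from 7.07 ± 0.07 (SD, n = 4) to 7.74 ± 0.27 (SD, n = 5) on control chow and from 7.08 ± 0.11 (SD, n = 5) to 7.95 ± 0.24 (SD, n = 5) on ibuprofen chow. Ccl3 rose by 0.71 ± 0.11 (SE, adjusted p = 0.0137), and Arpp21 fell by 0.23 ± 0.04 (SE, adjusted p = 0.0345). Prnp and App were the other genes. Rtl3, a gene derived from a retrotransposon, gave -0.74 ± 0.14 (SE, adjusted p = 0.0563).

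Genes of plaque-associated microglia stood out in this average. Of 37, 29 lay above 0 with a median of 0.13, 2 were called over all genes and 15 were higher adjusted over the list alone. Camera gave adjusted p = 1.28e-15, fry adjusted p = 0.0358, and camera adjusted p = 0.0788 with an estimated correlation. Clec7a, a lectin receptor of these cells, gave 0.22 ± 0.05 (SE, adjusted p = 0.232), the protease gene Ctsd 0.24 ± 0.06 (SE, adjusted p = 0.272), Tyrobp 0.19 ± 0.07 (SE, adjusted p = 0.515), Itgax 0.17 ± 0.09 (SE, adjusted p = 0.66) and Trem2 0.13 ± 0.05 (SE, adjusted p = 0.583). Among reactive astrocyte genes, 20 of 23 lay above 0 (median 0.12) and 5 were higher adjusted over the list alone, with 0 called over all genes. Their camera adjusted p was 3.32e-08, and adjusted p = 0.375 with an estimated correlation. Gfap, the filament protein of astrocytes, gave 0.49 ± 0.11 (SE, adjusted p = 0.211) and Serpina3n 0.35 ± 0.10 (SE, adjusted p = 0.354). Complement and Fc receptor genes (median 0.14, 3 of 15 higher adjusted over the list alone) and microglia and macrophage markers (median 0.14, 5 of 12) passed too, each with adjusted p = 0.375 with an estimated correlation. C4b, a complement component, gave 0.36 ± 0.12 (SE, adjusted p = 0.436).

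In all, 14 of 35 lists passed as higher and 5 as lower in the average genotype comparison, 0 with an estimated correlation and 1 with fry. Cholesterol synthesis (median 0.12), antigen presentation (0.08), the type I interferon response (0.12), oligodendrocytes (0.08), endothelial cells (0.06), mural and meningeal cells (0.11), homeostatic microglia (0.04), perivascular macrophages and blood leukocytes (0.04), and prostaglandins and eicosanoids (0.04) were the other higher lists. Lower were immediate early genes (median -0.06), glucocorticoid-responsive genes (-0.07), the circadian clock (-0.08), neocortex and subiculum (-0.09) and dentate granule cells (-0.15). Their adjusted p lay between 0.375 and 0.597 with an estimated correlation. The dentate list holds Tdo2 and is not independent evidence. It had 0 members called over all genes and 8 lower adjusted over the list alone, and without Tdo2 a median of -0.15 and 7 lower. Of the 19 calls 10 held in every leave-out, and 8 of these under every alternative at the preset correlation as well, all but choroid plexus with its own covariate (adjusted p = 0.802) and immediate early genes with array weights (adjusted p = 0.0542). Those of homeostatic microglia, interferon, prostaglandins, glucocorticoid-responsive genes, the clock, perivascular macrophages, oligodendrocytes, endothelial cells and mural cells ended (adjusted p = 0.0507 to 0.251) without 1 or more of APP-PS1 control chow replicates 1, 4 and 5, APP-PS1 ibuprofen chow replicates 1, 3 and 4, wild-type control chow replicates 1 to 4 and wild-type ibuprofen chow replicates 1 to 5. Choroid plexus markers, which varied together by array, passed as higher too (median 0.47, 17 of 17 above 0, adjusted p = 0.542 with an estimated correlation). Their median was 0.30 without APP-PS1 control chow replicate 4 and 0.76 without wild-type ibuprofen chow replicate 5. Over the leave-outs the other medians that moved by over 1.5 times ran from 0.07 to 0.17 for cholesterol synthesis, 0.03 to 0.10 for endothelial cells, -0.09 to -0.02 for glucocorticoid-responsive genes, 0.01 to 0.05 for homeostatic microglia, 0.05 to 0.18 for mural and meningeal cells, 0.02 to 0.08 for perivascular macrophages, 0.01 to 0.05 for prostaglandins and 0.05 to 0.18 for the interferon response.

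For this average limma called 5 genes, beside 1535 at an unadjusted p under 0.05, and 8 without the 3 arrays that stand apart, 4 of them shared. The count was 52 without APP-PS1 ibuprofen chow replicate 2, 3 without wild-type control chow replicate 4, where Ccl3 had adjusted p = 0.0629, and 8 without wild-type ibuprofen chow replicate 5. The count at an unadjusted p under 0.05 was 1002 without wild-type control chow replicate 3 and 2340 without wild-type ibuprofen chow replicate 4. The call of Arpp21 ended when any of 12 arrays was left out, with adjusted p from 0.0637 to 0.117, and without the 3 arrays that stand apart (adjusted p = 0.0723, in a range of 0.00119 to 0.0993 over the alternatives).

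The next question was what ibuprofen does in APP-PS1 hippocampus. No gene passed. Penk, the proenkephalin gene (probe set 10511363), had the smallest p, at 11.41 ± 0.13 (SD, n = 5) on control and 12.16 ± 0.39 (SD, n = 5) on ibuprofen chow, a difference of 0.75 ± 0.13 (SE, adjusted p = 0.168) with every treated array above every control array. Tdo2, the tryptophan dioxygenase gene that dentate granule cells express (probe set 10498921), gave -1.33 ± 0.28 (SE, adjusted p = 0.527) and Dsp, the desmoplakin gene and a granule cell marker (probe set 10404649), -0.93 ± 0.19 (SE, adjusted p = 0.527). For each of these, 5 of 5 treated arrays lay below the control mean.

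Dentate granule cell genes fell as a list in APP-PS1 mice on ibuprofen with the preset correlation. Of 15, 12 lay below 0 (median -0.20), 0 were called over all genes and 8 were lower adjusted over the list alone, with camera adjusted p = 1.61e-05 and adjusted p = 0.540 with an estimated correlation. This list holds Tdo2 and is not independent evidence, and without Tdo2 the median was -0.17, 7 genes were lower adjusted over the list alone and adjusted p = 0.540 with an estimated correlation. Markers of striatum, a list that holds Penk, rose on the same terms, with 10 of 10 above 0 (median 0.12), 2 higher adjusted over the list alone and adjusted p = 0.199 with an estimated correlation. Its second gene was Drd1, a dopamine receptor, at 0.46 ± 0.12 (SE). Genes of plaque-associated microglia (median 0.07, 30 of 37 above 0), microglia and macrophages (0.11), complement and Fc receptors (0.10), cytokines and chemokines (0.09), perivascular macrophages and blood leukocytes (0.09) and reactive astrocytes (0.06) passed as higher. The mitochondrial respiratory chain (median -0.07, 25 of 26 below 0), the circadian clock (-0.10), oligodendrocytes (-0.09) and sex-linked genes (-0.30, 4 of 4 below 0) passed as lower. These lists had adjusted p from 0.397 to 0.601 with an estimated correlation. Of the 12 calls 8 held in every leave-out, and those of reactive astrocytes, the clock, oligodendrocytes and sex-linked genes ended (adjusted p = 0.0522 to 0.792) without APP-PS1 control chow replicate 2, 3 or 5, APP-PS1 ibuprofen chow replicate 1, 3, 4 or 5, or wild-type ibuprofen chow replicate 5. Without APP-PS1 ibuprofen chow replicate 5 the medians of plaque-associated microglia and of microglia and macrophages were 0.03 and 0.05, and without replicate 4 that of cytokines was 0.05. Under every alternative at the preset correlation as well, 7 of the 8 held, and perivascular macrophages and blood leukocytes did not pass with array weights (adjusted p = 0.0677) or the oligodendrocyte covariate (adjusted p = 0.0519). Over the leave-outs the other medians that moved by over 1.5 times ran from 0.05 to 0.14 for complement and Fc receptors, -0.13 to -0.03 for oligodendrocytes, 0.05 to 0.11 for perivascular macrophages, 0.02 to 0.12 for reactive astrocytes and -0.35 to -0.15 for sex-linked genes.

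Cst7 gave 0.21 ± 0.11 (SE, adjusted p = 0.716) and Ccl3 0.06 ± 0.15 (SE, adjusted p = 0.897) on ibuprofen in APP-PS1 mice. Ptgs2, the inducible cyclooxygenase that ibuprofen inhibits, gave 0.04 ± 0.10 (SE, adjusted p = 0.914), and the list of prostaglandins and eicosanoids did not pass. Limma called 0 genes here, with 1292 at an unadjusted p under 0.05, and 0 without the 3 arrays that stand apart. In all, 7 lists passed as higher and 5 as lower, 0 with an estimated correlation and 0 with fry. The gene count was 3 without APP-PS1 ibuprofen chow replicate 2, namely Penk, Dsp and Tdo2 (each with adjusted p = 0.0177), and 1 without replicate 4 of that group, which was Penk (adjusted p = 0.0331). The count at an unadjusted p under 0.05 was 732 without that array, 804 without APP-PS1 control chow replicate 1 and 2070 without wild-type ibuprofen chow replicate 5.

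In wild-type hippocampus, the same diet comparison gave no gene and no list. Mir488, a microRNA gene, had the smallest p, at 0.40 ± 0.09 (SE, adjusted p = 0.432), and Iqgap2, a scaffold protein gene, gave 0.23 ± 0.05 (SE, adjusted p = 0.432). Against a median of 0.05 over all genes, dentate granule cell genes had 13 of 15 above 0 and a median of 0.17, with camera adjusted p = 0.0739 and adjusted p = 0.880 with an estimated correlation. This list holds Tdo2 and is not independent evidence. Without Tdo2 the camera adjusted p was 0.0392 at the preset correlation, but 0.880 with an estimated correlation. With Tdo2 the list passed at the preset correlation, the only one run in the leave-outs, when APP-PS1 control chow replicate 2, APP-PS1 ibuprofen chow replicate 2 or 3, wild-type control chow replicate 4, or wild-type ibuprofen chow replicate 1 or 5 was left out (adjusted p = 0.0229 to 0.0472). Limma called 0 genes, with 2198 at an unadjusted p under 0.05 and 692 without the 3 arrays that stand apart, where it also called 0 and 9 lists passed in place of 0. That count was 1218, 4564 and 926 without wild-type ibuprofen chow replicates 1, 4 and 5, and 1242 and 1382 without wild-type control chow replicates 3 and 4.

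Genotype was then compared on ibuprofen chow. Cst7 rose by 0.87 ± 0.11 (SE, adjusted p = 0.00101) and Penk by 0.78 ± 0.13 (SE, adjusted p = 0.0128), in each case with 5 of 5 APP-PS1 arrays above every wild-type array, and Prnp and App rose as given above. Dsp fell by 1.29 ± 0.19 (SE, adjusted p = 0.00545), from 9.87 ± 0.36 (SD, n = 5) to 8.58 ± 0.41 (SD, n = 5), and Rtl3 fell by 1.21 ± 0.19 (SE, adjusted p = 0.0063), both in 5 of 5 arrays without overlap. Tdo2 fell by 1.46 ± 0.28 (SE, adjusted p = 0.0189), and Prox1, the transcription factor of granule cell identity (probe set 10361023), by 0.46 ± 0.08 (SE, adjusted p = 0.0128), each with 5 of 5 APP-PS1 arrays below the wild-type mean. Frzb, Lct, Fat4, Kcng3, Syt10, Mkx and Alox12b completed the 10 largest falls, between -0.67 and -0.56.

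Granule cell genes made 6 of the 50 that fell. Of 15 in the list, 14 lay below 0 (median -0.29, against -0.05 over all genes), 6 fell over all genes and 9 adjusted over the list alone. The 6 were Dsp, Tdo2, Prox1, Lct, Il16 at -0.51 ± 0.10 (SE) and Rfx3 at -0.32 ± 0.07 (SE). Camera gave adjusted p = 5.94e-07 and fry adjusted p = 0.0126, but camera gave adjusted p = 0.512 with an estimated correlation. The list holds Tdo2 and is not independent evidence, and without Tdo2 its median was -0.29, with 5 called, 8 lower adjusted over the list alone, fry adjusted p = 0.0180 and adjusted p = 0.512 with an estimated correlation. C1ql2, a synaptic protein gene of granule cells in the same list, gave 0.08 ± 0.09 (SE).

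**Figure D2:**
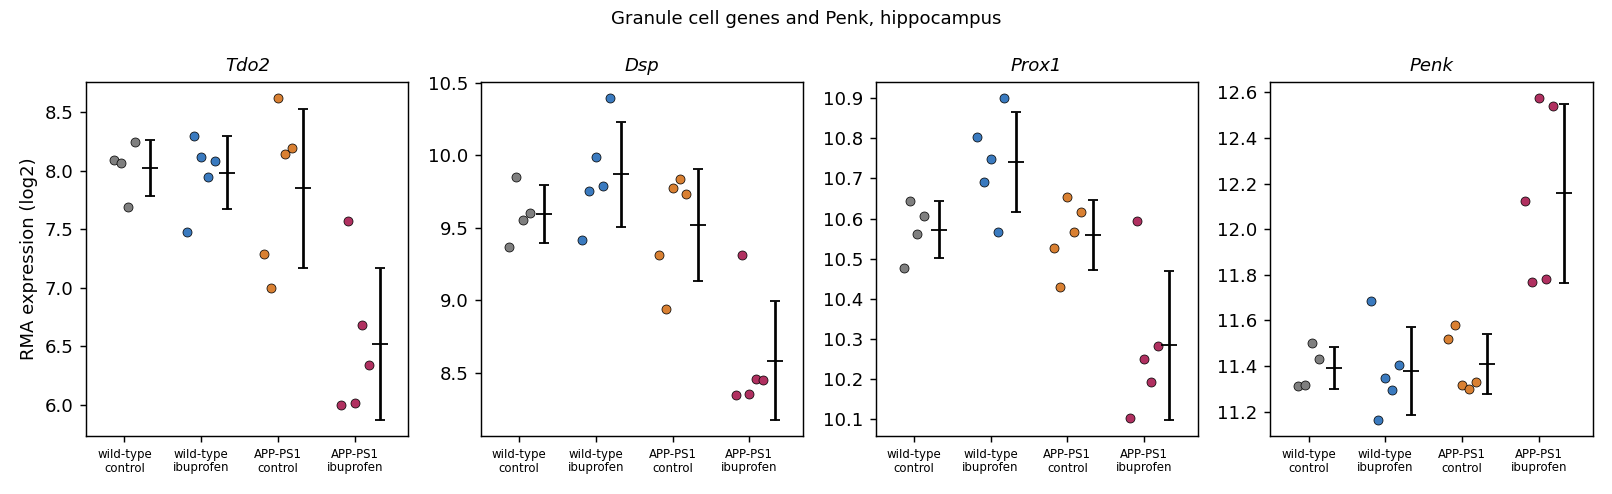
Log2 expression of Tdo2, Dsp, Prox1 and Penk in each array, by group; points are arrays and the dash with its bar is the group mean ± SD. In APP-PS1 mice on ibuprofen chow Tdo2 averaged 6.52 against 7.98 in wild-type mice on that chow, and Penk 12.16 against 11.38.

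Genes of plaque-associated microglia had 30 of 37 above 0 on ibuprofen chow (median 0.13), 1 called over all genes and 9 higher and 1 lower adjusted over the list alone, with camera adjusted p = 9.42e-09 and adjusted p = 0.512 with an estimated correlation. Reactive astrocyte genes had a median of 0.13 and 6 higher adjusted over the list alone, with Gfap at 0.56 ± 0.16 (SE), and adjusted p = 0.572 with an estimated correlation. Of 15 glucocorticoid-responsive genes, Mertk at -0.38 ± 0.07 (SE) and Bcl6 at -0.38 ± 0.08 (SE) fell over all genes and 5 adjusted over the list alone (median -0.12, adjusted p = 0.633 with an estimated correlation). Circadian clock genes (median -0.16, 7 lower and 1 higher adjusted over the list alone) and glutamate receptors and synapse genes (-0.06, 3 lower) passed as lower, both with adjusted p = 0.633 with an estimated correlation. Microglia and macrophages (0.11), antigen presentation (0.20), complement and Fc receptors (0.12), perivascular macrophages and blood leukocytes (0.11), striatum (0.07), the type I interferon response (0.21), mural and meningeal cells (0.10), and cytokines and chemokines (0.05) passed as higher, with adjusted p from 0.512 to 0.633 with an estimated correlation. Of the 15 calls 10 stayed past the threshold in every leave-out, though the median of mural and meningeal cells did not keep its sign. The calls of the clock, glucocorticoid-responsive, glutamate receptor, interferon and cytokine lists ended (adjusted p = 0.0549 to 0.238) without APP-PS1 ibuprofen chow replicate 1, 4 or 5 or wild-type ibuprofen chow replicate 2, 3 or 4. The clock call also ended with the replicate block (adjusted p = 0.0645), quantile normalization (median -0.07, adjusted p = 0.0964), the choroid plexus covariate (adjusted p = 0.121) and the dimmest genes left out (adjusted p = 0.285). The glucocorticoid call ended with the replicate block (adjusted p = 0.0645), array weights (median -0.01, adjusted p = 0.163) and the dimmest genes left out (adjusted p = 0.271). Choroid plexus markers passed as higher again, with 17 of 17 above 0, a median of 0.58 and adjusted p = 0.633 with an estimated correlation. Per array, their mean ran from 8.01 to 9.97 in APP-PS1 mice and from 7.67 to 10.19 in wild-type mice on ibuprofen chow. Without wild-type ibuprofen chow replicate 5 the median was 1.02 for choroid plexus, 0.21 for plaque-associated microglia, 0.22 for reactive astrocytes and -0.04 for glucocorticoid-responsive genes. Plaque-associated microglia had 0.09 without APP-PS1 ibuprofen chow replicate 5, and reactive astrocytes 0.09 without wild-type ibuprofen chow replicate 3. The antigen presentation median was 0.06 with the dimmest genes left out and 0.13 with the choroid plexus covariate. Of the 10 calls that stayed past the threshold in every leave-out, 8 held under every alternative run at the preset correlation. Choroid plexus (adjusted p = 0.685) and mural and meningeal cells (adjusted p = 0.0737) did not pass with the choroid plexus covariate. The mural median turned to -0.02 without APP-PS1 ibuprofen chow replicate 4 and reached 0.27 without wild-type ibuprofen chow replicate 5. Over the leave-outs the other medians that moved by over 1.5 times ran from 0.08 to 0.19 for complement and Fc receptors, 0.01 to 0.09 for cytokines, 0.05 to 0.16 for microglia and macrophages, 0.06 to 0.17 for perivascular macrophages, 0.05 to 0.12 for striatum and 0.07 to 0.26 for the interferon response.

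On ibuprofen chow limma called 4 genes higher and 50 lower, with 4876 at an unadjusted p under 0.05. Without the 3 arrays that stand apart it called 13 higher and 20 lower, 21 of them shared, and all 54 kept their direction. The count at an unadjusted p under 0.05 was 1985 without these 3, 3105 without APP-PS1 ibuprofen chow replicate 4, and 2961 and 2958 without wild-type ibuprofen chow replicates 1 and 5. The count of calls was 100 without APP-PS1 control chow replicate 1. Among APP-PS1 ibuprofen chow arrays it was 33 without replicate 1, 444 without replicate 2, 27 without replicate 3, 10 without replicate 4 and 30 without replicate 5, and among wild-type ibuprofen chow arrays 33 without replicate 3, 1490 without replicate 4 and 34 without replicate 5. Of 19 named genes that passed, 6 did so in each of these leave-outs, namely Cst7, Penk, Prnp, App, Dsp and Rtl3. Tdo2 did not pass without the 3 arrays that stand apart (adjusted p = 0.0508), nor without APP-PS1 ibuprofen chow replicate 1, 3, 4 or 5 or wild-type ibuprofen chow replicate 2, 3 or 5 (adjusted p = 0.0529 to 0.0795). Prox1 did not pass without the 3 arrays (adjusted p = 0.0734) or without APP-PS1 ibuprofen chow replicate 4 (adjusted p = 0.0532). That array also ended the calls of Fat4 (adjusted p = 0.0514), Mkx (adjusted p = 0.0532), Il16, Syt10, Alox12b, Kcng3, Mertk, Frzb, Lct, Rfx3 and Bcl6, and the last 9 depended on 3 to 13 arrays each, with adjusted p up to 0.152. With only the arrays of the 2 groups compared, 5 genes passed, and Penk (adjusted p = 0.152), Prox1 (adjusted p = 0.163) and Tdo2 (adjusted p = 0.0981) did not, while over the alternatives their adjusted p ran from 1.88e-05, 0.000789 and 0.000955 up to these values.

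Whether the effect of ibuprofen differed between genotypes was tested by the interaction. No gene passed, and the smallest p values belonged to Iqgap2 at -0.36 ± 0.07 (SE) and Cdh8, a cadherin gene, at -0.39 ± 0.07 (SE), with Jph1, a junctophilin gene, at -0.51 ± 0.11 (SE) among the 10 smallest, each with adjusted p = 0.208. Penk gave 0.76 ± 0.19 (SE), Dsp -1.21 ± 0.28 (SE), Tdo2 -1.29 ± 0.41 (SE) and Prox1 -0.44 ± 0.11 (SE), all with adjusted p = 0.208. Dentate granule cell genes had 15 of 15 below 0 (median -0.34, against -0.07 over all genes), with 0 called over all genes, 8 lower adjusted over the list alone and camera adjusted p = 0.000515. Without Tdo2, whose place in the list makes it not independent evidence, the median was -0.33, 7 were lower adjusted over the list alone and camera adjusted p = 0.00156. Both had adjusted p = 0.802 with an estimated correlation.

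Oligodendrocyte markers were lower in the interaction (median -0.21, against -0.07 over all genes, 12 of 12 below 0), and striatum markers (0.11), perivascular macrophages and blood leukocytes (0.17), cytokines and chemokines (0.08) and antigen presentation (0.15) higher. Each had adjusted p = 0.802 with an estimated correlation. These made 6 lists, 0 with fry, and 3 of them held in every leave-out, namely dentate granule cells, striatum and perivascular macrophages. With the oligodendrocyte marker mean as a covariate, 3 did not pass: perivascular macrophages and blood leukocytes (median 0.05, adjusted p = 0.0814), antigen presentation (0.01, adjusted p = 0.0509) and oligodendrocytes themselves (-0.03, adjusted p = 0.286). The oligodendrocyte call ended when APP-PS1 control chow replicate 2 or 3, APP-PS1 ibuprofen chow replicate 3 or 4, wild-type control chow replicate 1 or wild-type ibuprofen chow replicate 2 or 4 was left out (adjusted p = 0.0521 to 0.128). The antigen presentation call ended without APP-PS1 control chow replicate 1, 2 or 3, APP-PS1 ibuprofen chow replicate 3, wild-type control chow replicate 2 or wild-type ibuprofen chow replicate 2, 3 or 4 (adjusted p = 0.0523 to 0.140), and that of cytokines without APP-PS1 control chow replicate 2 or wild-type ibuprofen chow replicate 3 or 4 (adjusted p = 0.0515 to 0.0637). The antigen presentation median was 0.02 without wild-type control chow replicate 2, 0.07 and 0.08 without APP-PS1 ibuprofen chow replicates 3 and 4, 0.08 without wild-type ibuprofen chow replicate 3, and 0.24 to 0.28 without APP-PS1 control chow replicate 4 or 5, APP-PS1 ibuprofen chow replicate 2, wild-type control chow replicate 1 or wild-type ibuprofen chow replicate 5. That of cytokines was 0.03, 0.04 and 0.12 without wild-type ibuprofen chow replicates 3, 4 and 5, and that of striatum 0.16 without wild-type control chow replicate 1 or wild-type ibuprofen chow replicate 5. Other alternatives ended the calls of oligodendrocytes (median centring and the dimmest genes left out, adjusted p = 0.0591 and 0.175), antigen presentation (every probe set, adjusted p = 0.0838) and cytokines (every probe set, quantile normalization and the dimmest genes left out, adjusted p = 0.0838 to 0.113). Limma called 0 genes, with 4087 at an unadjusted p under 0.05, and 0 without the 3 arrays that stand apart, where 15 lists passed and 1836 genes had an unadjusted p under 0.05. Without APP-PS1 ibuprofen chow replicate 2 it called 13.

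The 50 genes lower in APP-PS1 mice on ibuprofen chow, among them Dsp and Prox1, had a median of -0.43 in that comparison and -0.0037 on control chow. For ibuprofen all 50 lay below 0 in APP-PS1 mice (median -0.26) and 48 above 0 in wild-type mice (median 0.16), but these comparisons share arrays with the one the genes were chosen in. Across all genes, the ibuprofen effects in the 2 genotypes correlated at r = -0.52, and 26.0% of genes had the same sign. The 3 arrays that stand apart lie in the APP-PS1 control and wild-type ibuprofen groups, which enter these effects with opposite sign. Without APP-PS1 control chow replicate 1 r was -0.34, and it was not computed without all 3, so opposite responses of the genotypes are not established. Genes are not independent replicates, and of 100 exchanges of the diet labels within genotype, the real one included, 3 gave an r as low, and the others ran from -0.64 to 0.57.

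**Figure D3:**
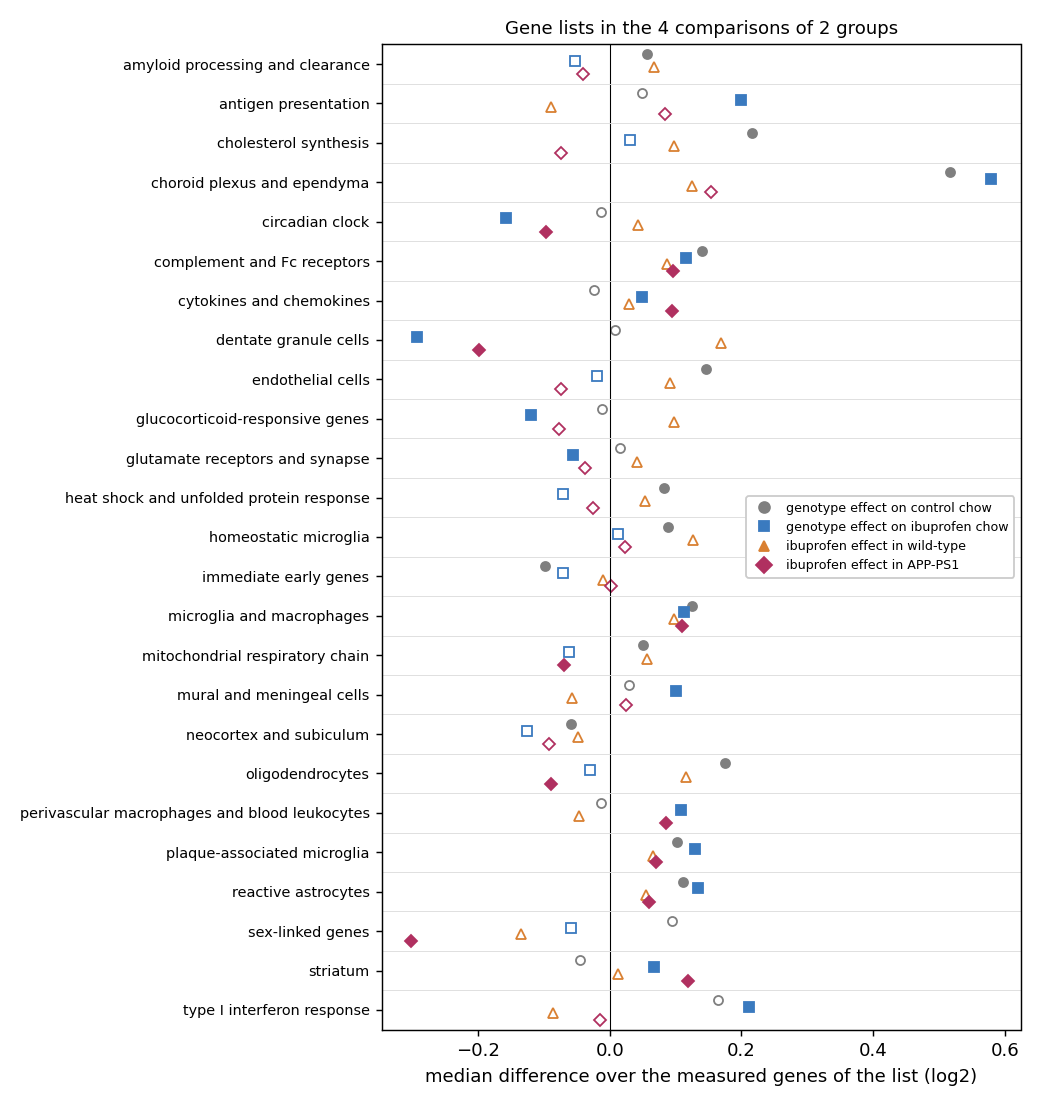
Median log2 difference of each gene list in the 4 comparisons of 2 groups; filled points are lists with a camera adjusted p under 0.05 at the preset correlation. The dentate granule cell list stood at -0.29 for genotype on ibuprofen chow and at 0.01 on control chow.

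Averaged over both genotypes, ibuprofen changed no gene. Plpp4, a lipid phosphatase gene, gave 0.36 ± 0.08 (SE) and Penk 0.37 ± 0.09 (SE), both with adjusted p = 1. Microglia and macrophages (median 0.10), complement and Fc receptors (0.10), plaque-associated microglia (0.07), homeostatic microglia (0.06) and striatum (0.07) passed as higher lists. Against a median of 0.01 over all genes, the lower lists were thalamus and habenula (median -0.07), neocortex and subiculum (-0.06), sex-linked genes (-0.21), dentate granule cells (-0.02), the circadian clock (-0.02), the mitochondrial respiratory chain (-0.0088) and immediate early genes (-0.0043). These 12 lists had adjusted p from 0.240 to 0.832 with an estimated correlation, and 0 passed with fry. Of them 6 held in every leave-out, and those of homeostatic microglia, immediate early genes, the clock, the respiratory chain, dentate granule cells and striatum ended (adjusted p = 0.0516 to 0.773) without 1 or more of APP-PS1 control chow replicates 3 to 5, APP-PS1 ibuprofen chow replicates 1 to 4, wild-type control chow replicates 2 to 4 and wild-type ibuprofen chow replicates 1, 2 and 4. The dentate list holds Tdo2, is not independent evidence and did not pass without it (camera adjusted p = 0.286). Limma called 0 genes, with 347 at an unadjusted p under 0.05, and 0 without the 3 arrays that stand apart, with 605. That count was 692 without APP-PS1 control chow replicate 1 and 671 without wild-type ibuprofen chow replicate 3. The 6 lists that held in every leave-out held under every alternative at the preset correlation too. Over the leave-outs the medians that moved by over 1.5 times ran from -0.05 to 0.02 for immediate early genes, -0.05 to 0.01 for dentate granule cells, -0.06 to -0.01 for the clock, -0.03 to -0.0001 for the respiratory chain, 0.03 to 0.08 for homeostatic microglia, 0.03 to 0.08 for striatum, 0.03 to 0.08 for plaque-associated microglia, -0.10 to -0.03 for neocortex and subiculum and -0.25 to -0.13 for sex-linked genes.

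The last question was whether ibuprofen returns the genes changed by genotype, such as Cst7 and Ccl3, toward their wild-type level. Over the 5 genes called in the average genotype comparison, the slope of the ibuprofen effect in APP-PS1 mice on the genotype effect on control chow was -0.0042. In 2000 simulations with these genotype effects and no ibuprofen effect it averaged -0.016, with 95% between -0.19 and 0.15, so it gives no sign of a return and excludes none inside that range. None of the 5 passed for ibuprofen in APP-PS1 mice, and differences between them were not tested. App and Prnp carry signal tied to the transgenes, so the slope and its range rest in part on genes that ibuprofen may be unable to return. Without them the slope was 0.014 over 3 genes, for which no range was simulated. Across all genes the correlation of these effects was -0.53, but they share the APP-PS1 control arrays with opposite sign, and simulated data without any effect gave -0.47. With those arrays split between the effects the correlation averaged -0.17 over 20 splits, from -0.39 to 0.18.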

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

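Of the tests in this part, those of a dependence on diet and of the spread of all dentate genes were chosen only after their results were seen, and so was leaving out the 3 arrays that stand apart.

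Dentate granule cell genes were lower in APP-PS1 than in wild-type mice on ibuprofen chow, with a median of -0.29 that passed camera at the preset correlation but not with an estimated correlation (adjusted p = 0.512), and Dsp, Tdo2 and Prox1 were among them. Less dentate gyrus in the dissected tissue stays open: C1ql2 minus Dsp was 2.26 ± 0.43 (SD, n = 5) in APP-PS1 and 0.90 ± 0.43 (SD, n = 5) in wild-type arrays (exact permutation test over 252 splits, two-sided p = 0.0159), but this sets a gene picked for its large fall against the only member not below 0. The 15 members differed by more than a fall shared by all would give (SD of their differences 0.42, exact permutation p = 0.0159; 0.20 without Dsp and Tdo2, exact permutation p = 0.0238), but 14 of 15 fell, and how far each is confined to granule cells was not measured. At the preset correlation, without the 3 arrays that stand apart the median was -0.32 (camera adjusted p = 5.57e-09), and with the choroid plexus marker mean as a covariate it was -0.32, which argues against each of these as the whole cause. With the Xist and Y-linked covariate it was -0.29 (camera adjusted p = 1.59e-07). Eif2s3y, a Y-linked gene, averaged 10.369 ± 0.535 (SD, n = 5) in APP-PS1 and 10.496 ± 0.458 (SD, n = 5) in wild-type mice on ibuprofen chow. With this gene expressed in both groups, that covariate gives no clear contrast of the sexes, so it does not test sex. A change of granule cell state may be a candidate explanation that cannot be told apart from less dentate tissue, litter was not tested, and a dependence on diet stays open, since the interaction median of -0.34 passed camera at the preset correlation (adjusted p = 0.000515) but had adjusted p = 0.802 with an estimated correlation.

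Arpp21 was lower in every APP-PS1 array than in every wild-type array on control chow, by a difference of -0.34. Among the 10 measured genes on each side of it on the chromosome, 0 of 20 had an unadjusted p under 0.05 for the average genotype effect, where the median of 19507 such windows was 1 and the 95th percentile 4. This gives no sign of a change shared with its neighbours. With a median of 1, a count of 0 has little room to differ from other windows, so it does not exclude a small shared change. Of the 3 arrays that stand apart, only APP-PS1 control chow replicate 1 enters this difference. Without the 3 the difference was -0.33, which argues against that array as its cause. Leaving out the wild-type ibuprofen chow arrays could not change this difference. On ibuprofen chow Arpp21 stood at 11.23 ± 0.055 (SD, n = 5) in wild-type and 11.11 ± 0.11 (SD, n = 5) in APP-PS1 mice. There 4 of 5 APP-PS1 arrays lay below the wild-type mean, and the groups overlapped. A transgene inserted in or beside Arpp21 is a candidate explanation that could not be tested here, and a response of neurons to amyloid is another.

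Other splits of the samples were compared with the real groups, 100 for each count, the real one included. For the genotype effect on control chow 1 split called as many genes (2 in the real split, 1 in the highest other). Those 2 were App and Prnp, which are tied to the transgenes, so this count can only show that the labels follow the transgenes. For the average genotype effect 1 split called as many (5, and 0 in the highest other). Those 5 were App and Prnp again, beside Cst7, Ccl3 and Arpp21. App and Prnp alone exceed the highest other split, so this count does not by itself exclude chance for Cst7, Ccl3 and Arpp21. On ibuprofen chow 3 splits called as many, 54 in the real split and 4392 in the highest other. Splits with several times the real count point to a structure of the samples that the groups do not explain, so this count alone does not exclude chance. For genes at an unadjusted p under 0.05, 3 splits gave as many for genotype on control chow (1170 real, 1538 highest other). This count was not among the tests set beforehand for genotype. It was 400 without wild-type control chow replicate 3, so it does not exclude chance. By such counts chance could not be excluded for genotype on ibuprofen chow either, where 8 splits gave as many (4876 and 8292). The same held for the average genotype effect, where 11 did (1535 and 3345), and for the other comparisons. Ibuprofen gave as many in 8 splits in APP-PS1 mice (1292 real, 3023 highest other), in 26 in wild-type mice (2198 and 5472) and in 76 as an average (347 and 5880). The interaction gave as many in 5 (4087 and 7202), and its highest other split called 1655 genes past the threshold against 0 in the real one, which points to the same structure.

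Single arrays lay far from the rest of their group in 13 of 184 tests of a gene in a group, where chance gives about 1 in 20. In APP-PS1 control chow replicate 1, Serpina3n was 12.48 (others 12.07 to 12.13), Ptgs2 11.49 (10.93 to 11.09) and Hmgcs1 12.06 (11.56 to 11.66), and in replicate 2 Arpp21 was 11.13 (10.95 to 10.99). In APP-PS1 ibuprofen chow replicate 2, Dsp was 9.31 (8.35 to 8.46) and Drd1 8.81 (9.26 to 9.39), and in replicate 3 Frzb was 8.45 (9.25 to 9.53). In wild-type ibuprofen chow replicate 5, Syt10 was 10.53 (10.06 to 10.14) and Mkx 9.49 (9.02 to 9.15), and in replicate 4 Cst7 was 7.27 (6.99 to 7.06). In wild-type control chow replicate 2, Mal was 11.65 (11.45 to 11.47) and Vmn1r48 5.46 (5.21 to 5.23), and in replicate 4 App was 13.16 (13.21 to 13.22).

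For the interaction, 6 lists passed camera at the preset correlation of 0.01. Their estimated correlations were higher, from 0.085 to 0.513, so a difference of the ibuprofen effect between genotypes is not established. The interaction medians were -0.34 for dentate granule cells, -0.21 for oligodendrocytes, 0.11 for striatum, 0.17 for perivascular macrophages and blood leukocytes, 0.15 for antigen presentation and 0.075 for cytokines and chemokines, all with adjusted p = 0.802 with an estimated correlation. Probe sets outside the gene table also passed limma's threshold when every probe set was fitted. Without a gene symbol here there were 1 for genotype on control chow, 1 for ibuprofen in wild-type mice, 13 for genotype on ibuprofen chow and 2 for the average genotype effect, and 4 more on ibuprofen chow were other probe sets of tested genes.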

How the results depend on the processing

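Leaving out the 3 arrays that stand apart was chosen only after the result was seen, and the other alternatives were planned. Over the named genes, 3186 of 3437 values under alternatives and leave-outs kept their direction and their side of the threshold, 134 fell short of it, 111 passed it and 6 reversed. Over the gene lists these were 894 of 959, 55, 8 and 2. Of 78 list calls, 43 stayed past the threshold in every leave-out, though among them the mural and meningeal median for genotype on ibuprofen chow did not keep its sign. At the preset correlation, the alternatives that ended most were the oligodendrocyte (18 ended, 18 added) and choroid plexus covariates (17 and 5), the dimmest genes left out (16 of 74 and 22), array weights (13 and 41) and quantile normalization (13 and 10). With an estimated correlation none of the 78 calls held. The number of arrays and their signal over background limit what can be called, and changes of 0.25 on the log2 scale were mostly missed in simulated data.

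Array weights gave 8 genes for genotype on control chow, 108 for ibuprofen in APP-PS1 mice, 2 for ibuprofen in wild-type mice, 1004 for genotype on ibuprofen chow, 174 for the interaction and 342 for the average genotype effect. Fitting every probe set gave 1 for ibuprofen in wild-type mice, and Ccl3 lost its average genotype call (adjusted p = 0.0703, in a range of 3.27e-06 to 0.0703 over the alternatives). Quantile normalization gave 8 for the average genotype effect. On ibuprofen chow genotype gave 149 with the dimmest genes left out, where fewer genes were tested, 91 with robust hyperparameters, 33 without the 3 arrays that stand apart and 5 with only the groups compared, where fewer samples estimate the spread. Without those 3 arrays the average genotype effect gave 8. Beyond what is said of genes tested and samples, the cause was not tested.

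The samples were treated as unpaired, since after removing group means not every pair of arrays with the same replicate number correlated above 0.1. Of these 17 of 27 pairs did (median 0.129), against 29 of 108 with different numbers (median -0.047), and 11 of 19 arrays had a same-number array as best partner, a hint from the data of a structure shared by number. The rule used does not exclude pairing, and neither the main fit nor the splits of the samples took account of such a structure. With the number as a replicate block, 4 genes passed for genotype on control chow and 197 on ibuprofen chow. It ended 7 of the 78 list calls and added 16. Those ended were choroid plexus (median 0.22, adjusted p = 0.462) and homeostatic microglia (adjusted p = 0.0732) on control chow, the circadian clock, glucocorticoid-responsive and glutamate receptor lists for genotype on ibuprofen chow (adjusted p = 0.0645 each), and endothelial cells (adjusted p = 0.123) and prostaglandins (adjusted p = 0.0749) for the average genotype effect.

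Leaving out each array in turn gave 2 to 4 genes for genotype on control chow, 0 to 3 for ibuprofen in APP-PS1 mice, 0 to 0 in wild-type mice, 10 to 1490 for genotype on ibuprofen chow, 0 to 13 for the interaction, 3 to 52 for the average genotype effect and 0 to 0 for the average ibuprofen effect. Lists past the threshold numbered 0 with an estimated correlation in each comparison, and with fry 0 in each except genotype on ibuprofen chow (1) and the average genotype effect (1). Without the 3 arrays that stand apart there were 9 for ibuprofen in wild-type mice and 15 for the interaction.

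The correlation of genotype and ibuprofen effects was -0.17 with the control arrays split, which removes the arrays they share, -0.46 with quantile normalization and -0.62 to -0.37 over the leave-outs. That of the ibuprofen effects in the 2 genotypes was -0.42 with quantile normalization and -0.57 to -0.34 over the leave-outs. With the choroid plexus mean as a covariate, the choroid plexus median itself became -0.038 for genotype on ibuprofen chow and -0.0027 for the average genotype effect, since the covariate is built from those genes. Values near 0 changed sign for ibuprofen in APP-PS1 mice, where App became 0.014 with the Xist and Y-linked covariate. Over the leave-outs Ccl3 ran from -0.0056 without APP-PS1 control chow replicate 4 to 0.12 and was -0.0012 without APP-PS1 ibuprofen chow replicate 1, and Ptgs2 ran from -0.018 without APP-PS1 ibuprofen chow replicate 3 to 0.13 and was -0.011 without APP-PS1 control chow replicate 4. For genotype on ibuprofen chow C1ql2 ran from -0.0016 without wild-type ibuprofen chow replicate 4 to 0.14. Leaving out the dimmest genes moved the median of all genes to -0.13 in the interaction.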

Other observations

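Of the tests in this part, those of Penk, Tdo2 and Fos, and every test within diet, were chosen only after their results were seen.

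Several gene groups did not pass in any comparison. They were tryptophan and kynurenine metabolism (19 genes, lowest camera adjusted p = 0.519), PPAR target genes (19, 0.102), astrocytes (11, 0.368), oligodendrocyte precursors (10, 0.0978), blood (3, 0.158), CA1 pyramidal cells (9, 0.0801), CA2 and CA3 pyramidal cells (13, 0.0625) and GABAergic interneurons (14, 0.0517). The tryptophan list holds Tdo2, is not independent evidence, and without Tdo2 did not pass either. Among 245 pairs of a list and a comparison, the median, mean and test differed in sign in 33, and 0 of these passed.

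Calb1, the calbindin gene of granule cells, ran from 11.30 to 11.89 over the 10 APP-PS1 arrays, with means of 11.72 ± 0.19 (SD, n = 5) on control and 11.49 ± 0.15 (SD, n = 5) on ibuprofen chow. A shared granule cell state across APP-PS1 samples was tested as a hypothesis, with Pearson's r of 6 genes with Calb1, permutation tests (100000 permutations, two-sided) and Benjamini-Hochberg adjustment over the 6. Tdo2 correlated at r = 0.88 (permutation p = 0.00149, adjusted p = 0.00894; rho = 0.82, permutation p = 0.00572), Penk at r = -0.79 (permutation p = 0.00698, adjusted p = 0.0209; rho = -0.81, permutation p = 0.00712) and Npy, a neuropeptide gene, at r = -0.72 (permutation p = 0.0118, adjusted p = 0.0236; rho = -0.88, permutation p = 0.00171). Without the 2 arrays farthest from the median of Calb1, APP-PS1 control chow replicates 3 and 5, r was 0.77, -0.71 and -0.71. These tests ignore diet. With the diet means removed and Calb1 exchanged only within each diet (all 14400 exchanges), r was 0.82 for Tdo2 (exact permutation p = 0.0147, adjusted p = 0.0442) and -0.66 for Penk (exact permutation p = 0.0143, adjusted p = 0.0442), while Npy did not pass at -0.57 (exact permutation p = 0.0671, adjusted p = 0.134).

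The other genes did not pass for r in either test (within diet, adjusted p = 0.184 for Nptx2 and Fos and 0.239 for Inhba). Nptx2 gave r = -0.61 (permutation p = 0.0433, adjusted p = 0.0649; rho = -0.88, permutation p = 0.00163), Fos r = -0.61 (permutation p = 0.0625, adjusted p = 0.0750; rho = -0.68, permutation p = 0.0352), opposite in sign to Tdo2, and Inhba r = -0.35 (permutation p = 0.331, adjusted p = 0.331; rho = -0.39, permutation p = 0.263). The 3 genes chosen before their values were seen, Npy, Inhba and Nptx2, did not pass within diet, and the 2 that did were chosen after, so these values do not establish a shared granule cell state, and a difference in dissection that moves these genes together was not tested.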
